A study of Homo sapiens with 6 samples.

How the data were processed

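ATAC-seq of HEK293T cells was analysed in 6 libraries, 3 of wild-type and 3 of RNF111 S254A cells, all labelled with adavosertib. Per the labels' protocols, 50000 cells per library were lysed, nuclei were incubated with Tn5 transposase and the purified DNA was amplified by PCR. Per the submitters' processing notes, Bowtie2 and the genome build GRCh38 were used. The peak caller, its settings, read filters, duplicate handling and any shift of reads for the transposase are not given in the sources used here. The authors deposited 1 peak table per library, so peaks were called per library and not on pooled reads.

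Per the file headers, each row gives a peak's position, summit, pileup, fold enrichment, annotation and nearest gene with its distance. The deposited pileup is a coverage signal at the summit in whole numbers, read from its values as not scaled between libraries. The deposited fold enrichment is a ratio of pileup to the caller's local background. A pair of columns whose headers were lost held -log10 values of a p-value and of a q-value in the deposited tables, judged from their values and order; no q-value column entry lay below 1.30, which is a q-value of 0.05. These values are the authors' own per peak and were used to describe, rank or filter peaks within a list. Deposited folds, pileups and pileups relative to each library's own background floor (below) were also set side by side between libraries, as description. Rows that gave several summits of a peak were collapsed to 1 peak with its highest values. The tables hold only the 24 standard chromosomes. Gene symbols that a spreadsheet had turned into dates (27 genes) were replaced by their Ensembl identifiers.

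Depth could not be read from totals. As a stand-in, the background floor of a library was computed as the lowest value of (pileup + 1) / fold - 1, which is the caller's lowest local background. It scales with the number of reads if all libraries were called with the same settings, which the sources do not state. Differences smaller than the spread between the 3 libraries of a genotype were not detectable, and a region without a call can hold signal below the caller's threshold.

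Peaks of all libraries were merged where they overlapped by 1 bp or more, and a library called a region if it had a peak in it. A region's annotation was that of its strongest peak. A gene had a promoter peak if a peak overlapped the window of 1000 bp either side of the gene start given in the files, for 19229 genes; for genes with several starts this is the outermost one. Pileup divided by the background floor was used to describe signal over background. Group means were compared with an exact permutation test over all 20 assignments of the 6 libraries (two-sided, smallest p 0.1). Chromosomes and gene lists were adjusted by the Benjamini-Hochberg method. Gene lists among genes called in 1 genotype were tested with Fisher's exact test (two-sided) against genes with a promoter peak in every WT library, and against 10000 random lists matched on WT peak strength in 10 bins (seed 20). Overlap was the Jaccard index of covered bases.

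The 23 gene lists were fixed before the data were examined, with 774 entries, of which 709 matched a symbol in the files, 46 matched an older symbol, not in current use for another gene, through the RefSeq gene table (GRCh38.p14) and 19 matched none. The same table gave the spans of named genes. Genes named in the text were chosen by a rule fixed at the same time. They were RNF111, SKI, SKIL, SMAD7, XPC, UBE2M and WEE1 whatever their values; per direction the 10 genes with the highest smallest fold over the 3 libraries with the peak; up to 4 members of each list per direction; the 5 genes with the highest smallest fold over all 6 libraries; and per direction the 5 regions away from promoters with the highest smallest fold. The RNF111 exon regions beyond those 4, CDC20, CDC20P1, HBB, RNU6-1 and PGK1 were singled out after their values were seen. An item that the rule would name is not reported here. A planned search of 26 sequence motifs in peaks was not run, since no genome sequence was at hand.

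Alternatives were a stricter threshold (-log10 q of at least 5), the 59103 strongest peaks of every list (the length of the shortest), promoter windows of 500 and 2000 bp, the summit inside the window, coverage of at least 0.5 of a merged region, fixed windows of 500 bp, peaks of 500 bp around the summit, the replicate number as a block, and each library left out in turn. The functions were tested on simulated data. In 6 lists drawn from the 178779 peaks of WT replicate 1, all 200 regions made WT-only were recovered, beside 1698 that arose by chance where 1654 were expected, and a simulated odds ratio of 4 came back as 4.10. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.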

Results

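The data describe chromatin accessibility in HEK293T cells, a transformed human embryonic kidney line, measured with ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA. There were 3 wild-type (WT) libraries and 3 libraries of cells carrying the S254A form of RNF111 (SA), a change of serine to alanine. RNF111, also named Arkadia, is a ubiquitin ligase that acts in TGF-β signalling on SKI, SKIL and SMAD7 and that takes part in nucleotide excision repair. All 6 libraries carried the treatment label adavosertib, an inhibitor of the WEE1 kinase, and the series description names only the genotype. If the label holds for every library, the comparison is between genotypes under treatment; no library is labelled as untreated. Each library came from 50000 cells and was represented by its own list of called peaks. Read totals are not given in the sources used here; the caller's background floor, which scales with depth if all libraries were called with the same settings (not stated in the sources), was 2.17, 3.23 and 3.02 in WT replicates 1, 2 and 3, and 1.91, 4.33 and 1.82 in SA replicates 1, 2 and 3. SA replicate 2 therefore had the highest floor of the 6 and the other 2 SA libraries the lowest. With 3 libraries against 3, the exact permutation test cannot give a two-sided p below 0.1, so no difference between genotypes can pass 0.05 in that test. Nothing in the labels says that the replicates were separate cultures, and the p-values measure only the spread between these libraries.

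The mutated gene itself was examined first. RNF111 lies on chromosome 15 (ENSG00000157450, RefSeq span 58987663 to 59097419, GRCh38). A peak over its first exon, from 58987458 to 58988544 and annotated as 5′ UTR, was called in all 6 libraries, with pileups of 27, 45 and 45 in WT and 17, 44 and 21 in SA. Further into the gene, 13 regions between 59030770 and 59094963 were called in every SA library and in no WT library. All 13 carried an exon or UTR annotation, and no region in any library was called in the introns between them. The exon 6 peak (59066697 to 59067149) had pileups of 1586, 2849 and 1557 in SA replicates 1, 2 and 3, and over the 13 regions the SA pileups ranged from 191 to 2850. The gene table of the files places the RNF111 start at 58865175, where no library had a peak within 1 kb.

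**Figure D1:**
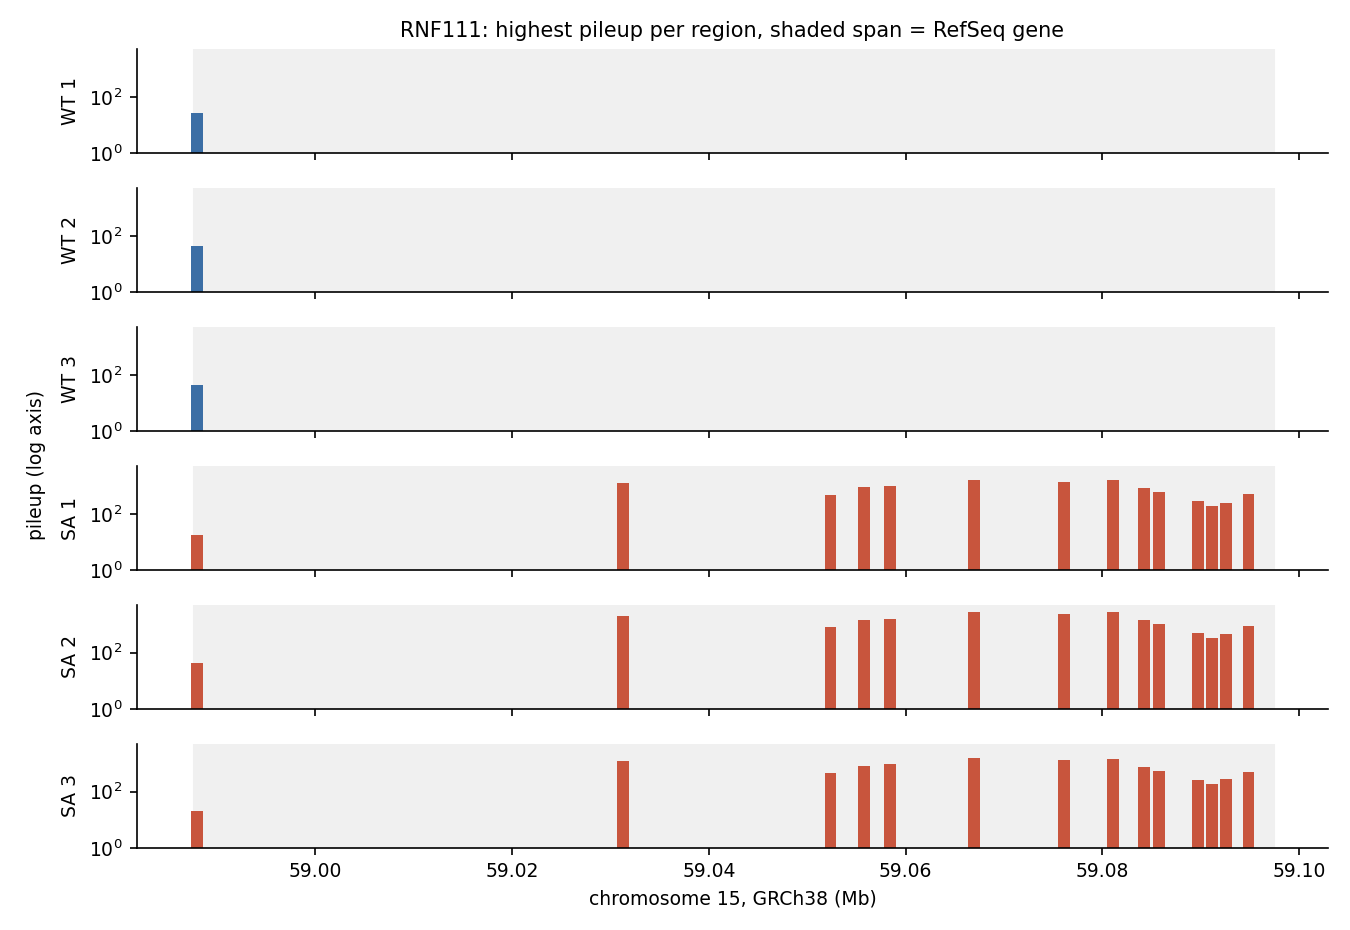
Highest peak pileup (log axis) in each called region of RNF111 against position on chromosome 15 (Mb, GRCh38), 1 panel per library, with the RefSeq gene span shaded and bars drawn wider than the peaks so that they can be seen. All 6 libraries have the first-exon peak, and the 13 exon regions are filled in the 3 SA libraries and empty in the 3 WT libraries.

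To ask how much accessible chromatin each genotype showed, peaks were counted per library. WT libraries held 178779, 243041 and 237258 peaks, and SA libraries 71212, 133342 and 59103. The means were 219693 ± 35550 in WT and 87886 ± 39829 in SA (SD, n = 3 each), a ratio of 2.50, and every WT library lay above every SA library (exact permutation test, two-sided p = 0.1, the smallest possible). Peaks covered 59.6 ± 9.12 Mb in WT and 24.4 ± 11.04 Mb in SA (n = 3 each; exact permutation p = 0.1), while the mean peak width was close in both, 271 ± 5.15 bp and 277 ± 4.69 bp (exact permutation p = 0.3). The median peak width was 220 ± 4.51 bp in WT and 207 ± 2.52 bp in SA (exact permutation p = 0.1). It was lower in every SA library than in every WT library. The difference in covered length, -35.2 Mb, was -5.14 Mb with lists of equal length and -65.1 Mb with peaks of 500 bp around the summit. In the 28304 regions called in all 6 libraries, the deposited fold enrichment had medians of 12.6, 11.9 and 14.7 in WT and of 6.18, 6.48 and 5.93 in SA. The median pileup in these regions, divided by the library's background floor, was 38.2, 31.8 and 47.0 in WT and 14.1, 13.4 and 13.7 in SA. The lower peak numbers of SA thus came with a lower signal over background in the same libraries, including SA replicate 2, whose floor was the highest.

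**Figure D2:**
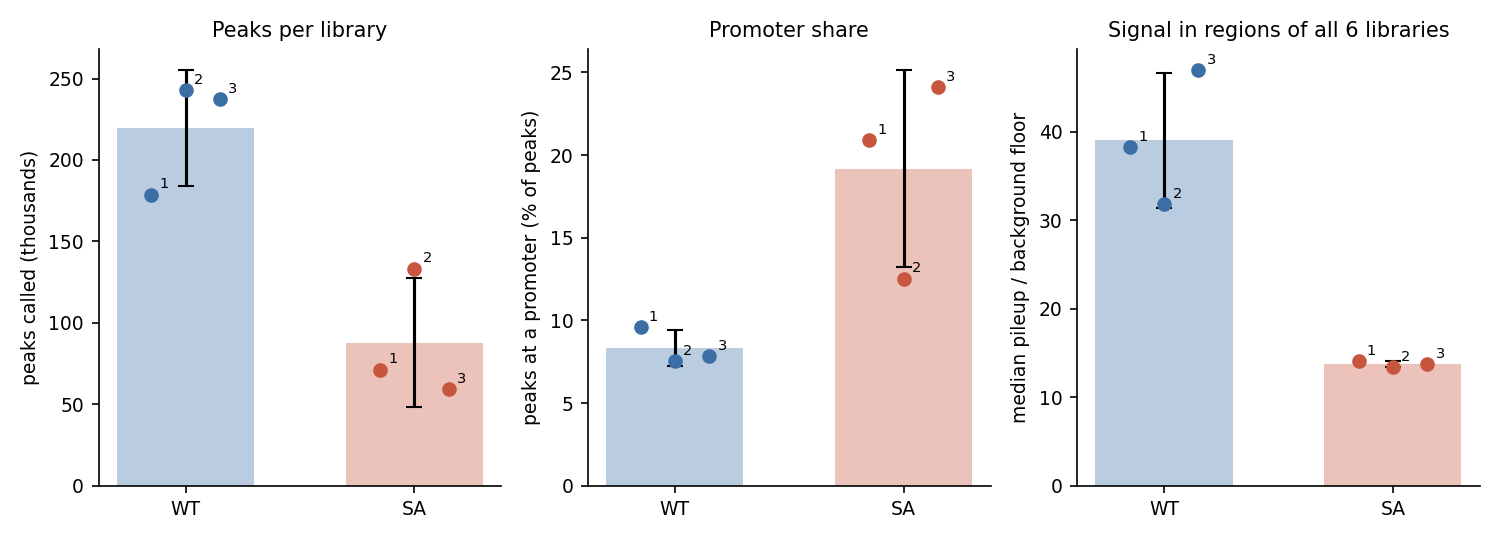
Peaks per library (in units of 1000 peaks), share of peaks at a promoter (% of peaks) and median pileup divided by the background floor in regions called in all 6 libraries. Points are libraries numbered by replicate, bars are means and error bars are SD (n = 3); SA libraries lie below every WT library in the first and last panel and above every WT library in the middle panel.

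Promoters made up a larger part of the SA peaks. Peaks within 1 kb of a gene start were 9.58%, 7.55% and 7.82% of the WT lists and 20.9%, 12.5% and 24.1% of the SA lists, with means of 8.31 ± 1.10% and 19.2 ± 5.97% (SD, n = 3 each; exact permutation p = 0.1); the difference of 10.9 percentage points was 19.1 at the stricter threshold (-log10 q of at least 5). In the files' own annotation, intron peaks were 36.6 ± 0.995% of WT and 29.6 ± 2.69% of SA peaks (n = 3 each; exact permutation p = 0.1), and distal intergenic peaks 46.7 ± 0.633% and 41.6 ± 4.15% (n = 3 each; exact permutation p = 0.2). The number of promoter peaks in that annotation was 23377 ± 1419 in WT and 17983 ± 2087 in SA, whereas intron peaks numbered 80542 ± 14769 and 26752 ± 14675, a ratio of 3.01 (SD, n = 3 each). Of 19229 genes, 14155 ± 434 in WT and 12446 ± 719 in SA had a promoter peak (SD, n = 3 each; exact permutation p = 0.1). When every list was reduced to its 59103 strongest peaks, the order of the gene counts turned, with 196 more genes in SA on average (exact permutation p = 0.4), and the promoter share remained higher in SA by 3.75 percentage points.

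Merging the peaks of all 6 libraries gave 448763 regions. Of the 99959 regions called in every WT library, 28304 (28.3%) were called in every SA library and 35134 (35.1%) in none. Of 28964 regions called in every SA library, 97.7% were called in every WT library and 137 (0.473%) in none. The 137 include the 13 RNF111 exon regions given above and regions over CDC20, HBB and an intron of TBC1D5 (described below). Regions without a WT call were more frequent in single SA libraries than in all of them together. Of the regions of SA replicates 1, 2 and 3, 75.1%, 66.0% and 77.8% were called in at least 1 WT library. In these replicates 15315, 41906 and 11304 regions were called in that library alone. Such regions were not particular to SA: 68525 (15.3% of all regions) were called in 1 SA library alone and 192115 (42.8%) in 1 WT library alone. The share without an SA call differed by annotation. Among regions called in every WT library, 1550 of 16470 promoter regions (9.41%) were called in no SA library, against 14324 of 33629 intron regions (42.6%) and 17458 of 43165 distal intergenic regions (40.4%). The count of 35134 was 60418 without WT replicate 1, and it was 7086 when the lists were reduced to equal length; the count of 137 was 50 at the stricter threshold, 826 at equal length and between 210 and 1154 without any one library other than WT replicate 1. Leaving a library out loosens the criterion, so such counts can hardly fall.

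**Figure D3:**
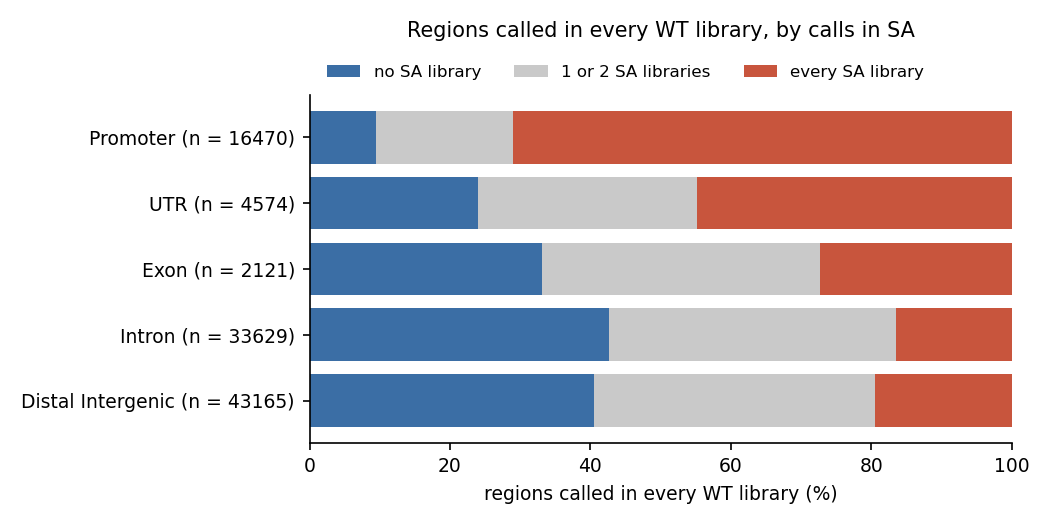
Regions called in every WT library (100% of each bar), split by whether no, some or every SA library called them, for 5 annotation classes with the number of regions in brackets. Promoter regions were called in every SA library in 71.1% of cases, and intron regions in 16.5%.

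The strongest regions away from promoters that were called in every WT and no SA library were a distal intergenic region on chromosome 2 (90105200 to 90105492; nearest annotated gene IGKV2D-28) whose lowest deposited fold over the WT libraries was 24.9, intron 5 of SLCO5A1 on chromosome 8 (69720928 to 69721212; lowest fold 23.9), a distal region near SMIM31 on chromosome 4 (164716895 to 164717253; 21.4), intron 22 of ITGA8 on chromosome 10 (15661002 to 15661353; 20.7) and a distal region on chromosome 2 (177106243 to 177106670; 20.4) whose nearest gene start was that of HNRNPA3. In the other direction, intron 14 of TBC1D5 on chromosome 3 (17402118 to 17402329) ranked first, with deposited folds of 55.3, 47.7 and 53.8 in SA. The other 4 were RNF111 exon regions, which the files assign to the nearest gene start, that of CCNB2.

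At the level of genes, 13103 had a promoter peak in every WT library, and 11298 of these (86.2%) had one in every SA library too. A promoter peak in every WT and no SA library was found for 448 genes (3.42%). The 10 with the strongest WT peaks were TDO2, LOXHD1, CCL8, F11, GJA10, QPCT, LRRC17, CXorf66, AC002996.1 and IL7R. TDO2, which encodes the tryptophan-degrading enzyme of the liver, had deposited folds of 24.1, 21.02 and 28.1 in WT replicates 1, 2 and 3. F11, coagulation factor XI, had folds of 18.6, 14.2 and 23.6, CCL8, a chemokine, of 15.1, 14.4 and 18.4, and LOXHD1, a gene of the inner ear, of 19.3, 17.6 and 21.4. IL7R, the interleukin 7 receptor of lymphocytes, had folds of 10.7, 15.1 and 13.4. Each window surrounds the outermost annotated start of a gene, at 155854762 for TDO2 and 35852695 for IL7R. Peaks at other starts outside that window were not counted. In the other direction a single gene, FAM47A on chromosome X, had a promoter peak in every SA and no WT library, with folds of 4.80, 4.50 and 3.90; it belonged to none of the 23 gene lists. Some of these calls depend on the window: with 500 bp the difference at LOXHD1, QPCT, GJA10, CXorf66 and F11 was 0, with 2 kb that at LOXHD1 and QPCT was 0 and that at GJA10 and LRRC17 smaller, and with the summit inside the window that at LOXHD1 and GJA10 was 0. FAM47A lost its full difference with 500 bp, with the summit inside the window and at the stricter threshold. For any single gene, 3 calls against 0 give an exact p of 0.1 at best. The count of 448 was 765 without WT replicate 1, 897 without SA replicate 2 and 104 with lists of equal length, where the count of 1 became 87. Without any one library other than WT replicate 1, the count of 1 was between 2 and 20. Counts with a library left out can hardly fall, since the criterion is then looser.

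Genes tied to RNF111 had promoter peaks in both genotypes. SKI, SKIL and SMAD7, its targets in TGF-β signalling, had a promoter peak in all 6 libraries, as did XPC, the DNA damage sensor of nucleotide excision repair, UBE2M, a NEDD8-conjugating enzyme, and WEE1. Deposited folds at XPC were 23.9, 22.8 and 27.4 in WT and 11.7, 13.3 and 12.6 in SA, and at WEE1 15.4, 10.6 and 11.8 in WT and 10.9, 10.5 and 8.98 in SA. At SKI they were 11.6, 10.2 and 13.1 in WT and 8.82, 7.78 and 8.74 in SA. SKIL had 11.6, 11.1 and 11.8 in WT and 8.41, 6.86 and 6.49 in SA. SMAD7 had 7.25, 5.75 and 5.84 in WT and 5.28, 5.30 and 5.61 in SA. UBE2M had 4.16, 4.41 and 6.33 in WT and 4.23, 3.80 and 4.46 in SA. The genotypes thus overlapped at WEE1 and UBE2M. Lower folds in SA were not particular to genes tied to RNF111. Over regions called in all 6 libraries, the mean of the library medians in SA was 0.473 of that in WT. The 5 genes whose promoter peaks were strongest in all 6 libraries were SRGAP2, FAM72A, FAM185A, FAM72B and SRGAP2C. SRGAP2 and FAM72A share a promoter peak and have near-identical copies in SRGAP2C and FAM72B, so reads of these copies may have been assigned to either.

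Gene lists fixed before the data were examined were compared by the share of members with a promoter peak, relative to all genes in the same library. In 12 of 23 lists the 3 SA libraries lay apart from the 3 WT libraries, and the smallest adjusted exact permutation p was 0.192. Chance gives 10% of lists only if the share of all genes is the same in both genotypes. That share was lower in SA, so a list that kept all its promoter peaks lies apart without a change of its own. Lists of widely used genes had nearly as many promoter peaks in SA as in WT while the count over all genes was lower in SA, and so stood higher relative to it. The WEE1-CDK cell cycle list had 31 of 32 members with a promoter peak in each of the 6 libraries, and its share relative to all genes was 23.3 percentage points in WT and 32.1 in SA. The p53 targets had 26 of 29 members in each library, and both lists shifted by 8.89 percentage points, which is the shift of all genes. Replication and its checkpoint (39 of 44 members in all 6 libraries), double-strand break repair (39 of 44), nucleotide excision repair (22 of 25), housekeeping genes (36 of 38), oxidative phosphorylation (32 of 35) and the replication-dependent histones (32 of 41) also stood higher in SA in every library. In none of these 8 lists was the mean number of members with a promoter peak higher in SA. Relative to all genes, 4 lists stood lower in SA. Blood cell genes had 8, 11 and 9 of 28 members with a promoter peak in WT and 5, 4 and 2 in SA, and the liver, muscle and skin list had 10, 11 and 11 of 28 in WT and 4, 7 and 5 in SA. Pluripotency genes (6, 5 and 6 of 16 in WT; 2, 4 and 2 in SA) and the interferon response (17, 22 and 20 of 29 in WT; 13, 16 and 14 in SA) were also lower in each SA library. Neural genes (24, 25 and 24 of 35 in WT, 19, 23 and 18 in SA) had lower counts in each SA library too. So did mesenchymal genes (19, 20 and 19 of 26 in WT, 17, 17 and 14 in SA). Relative to all genes, however, these lists did not separate the genotypes. At equal list length 3 of the 23 lists lay apart.

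**Figure D4:**
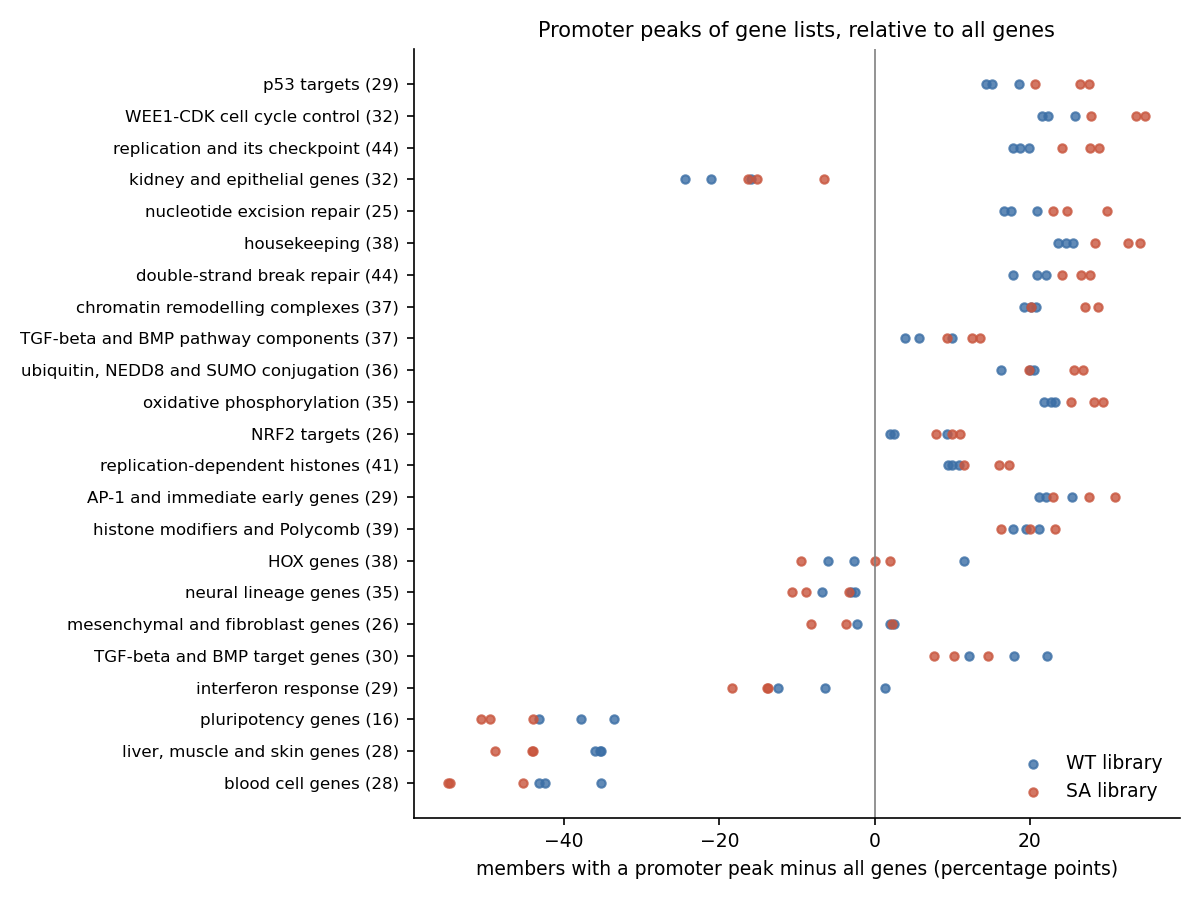
Share of list members with a promoter peak minus the share of all genes (percentage points) for 23 gene lists with the number of matched members in brackets; each point is a library. The WEE1-CDK list averaged 23.3 in WT and 32.1 in SA, and the blood cell list -40.3 in WT and -51.6 in SA.

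The remaining 11 lists did not separate the genotypes relative to all genes, the measure by which lists are judged in this paragraph. TGF-β and BMP target genes had 28, 26 and 28 of 30 members in WT and 22, 23 and 23 in SA (relative to all genes, exact permutation p = 0.2), and components of these pathways had 30, 29 and 30 of 37 in WT and 28, 29 and 28 in SA (exact permutation p = 0.2). AP-1 and immediate early genes (24 of 29 members in all 6 libraries), NRF2 targets (19 of 26), chromatin remodelling complexes (33 of 37), ubiquitin, NEDD8 and SUMO conjugation (32 of 36), histone modifiers and Polycomb (30 of 39), HOX genes (19 of 38), neural lineage genes (18 of 35), kidney and epithelial genes (13 of 32), and mesenchymal and fibroblast genes (14 of 26) overlapped between genotypes as well.

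Among the 448 genes, 1 list was over-represented. Of the 7 blood cell genes with a promoter peak in every WT library, IL7R, CD74 and CD4 had none in SA, against 3.40% of other genes (Fisher's exact test, two-sided p = 0.00125, adjusted p = 0.0288 over 23 lists). Random lists matched on WT peak strength gave 0.943 such genes on average, and against them the adjusted p was 0.948. The Fisher call was lost with a promoter window of 2 kb, at equal list length, and without WT replicate 1, WT replicate 2 or SA replicate 2. Other list members with a promoter peak in every WT and no SA library included ANGPTL4, PMEPA1, SMAD4, HOXD10, MTA1, IFIT2, IFI44L, APOB, FLG, DPPA2 and SP100. At equal list length the difference shrank or was 0 for all of these but ANGPTL4 and APOB, and was 0 for CD74 and CD4. At the stricter threshold it shrank or was 0 for HOXD10, IFI44L, MTA1, FLG and CD4. With a window of 500 bp it was 0 for ANGPTL4, PMEPA1 and APOB and smaller for FLG, with 2 kb it was 0 for ANGPTL4, PMEPA1 and SMAD4 and smaller for IFI44L, and with the summit inside the window it was 0 for ANGPTL4 and smaller for APOB. The windows at SMAD4 and IL7R, as at every gene, surround the outermost annotated start of the gene.

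On average, libraries of a genotype resembled each other more than those of the other genotype. The Jaccard index of covered bases averaged 0.399 within WT (0.387 to 0.413 over 3 pairs), 0.321 within SA (0.288 to 0.370 over 3 pairs) and 0.233 between genotypes (0.183 to 0.307 over 9 pairs). Single pairs overlapped: the index of SA replicate 2 was 0.307, 0.275 and 0.274 to WT replicates 1, 2 and 3, and 0.304 and 0.288 to SA replicates 1 and 3. The difference between pairs of the same and of different genotype was 0.127, the highest of the 10 splits of the 6 libraries (exact p = 0.1, the smallest possible), and 0.208 at the stricter threshold. The index is limited by list length, which differed between the genotypes. SA replicate 3 covered 16.7 Mb and WT replicate 3 covered 65.1 Mb, so their index would be low even if the shorter list lay wholly inside the longer. In the full lists the difference therefore cannot be assigned to genotype rather than to list length. With the 59103 strongest peaks of every list the difference kept its direction. Covered length still differed between the genotypes there, by -5.14 Mb. By chromosome, the share of peaks lay apart between genotypes for 8 of 24 chromosomes, where chance gives 10%, and no adjusted exact permutation p was below 0.3. The shares add up to the whole list, so chromosomes are not independent of each other. Whether they follow the higher promoter share of SA was not tested. Chromosome 19 held 2.49% of WT and 3.46% of SA peaks, chromosome 1 held 10.8% and 11.6%, and chromosome 2 held 7.83% and 7.31%.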

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

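The tests on the RNF111 exons, flanking peaks, the first-exon peak and the variation between SA libraries were chosen after the result was seen; the splits of the libraries were planned. Pileups in single regions, which were not tested between genotypes, held signals in SA far above WT. With a region counted when its lowest SA pileup, relative to the background floor, was at least 20 times the highest in WT (regions without a call set at 3 times the floor), 22 regions stood out in SA and 0 in WT. The 13 RNF111 exon regions had SA pileups of at least 191 and no WT call. CDC20, an activator of the anaphase-promoting complex, on chromosome 1 (43358981 to 43363203) had 4 such regions within its span (2 annotated as promoter, 1 as exon and 1 as 3′ UTR) with SA pileups of at least 1897. CDC20P1, its processed pseudogene on chromosome 9 (87011574 to 87013210), had at least 4760 in SA and a pileup of 13 in WT replicate 3 alone among WT. A region over the 3′ part of HBB, the β-globin gene, on chromosome 11 (5224856 to 5226177) had at least 20804 in SA and no WT call. The U6 small nuclear RNA gene RNU6-1 with its flank on chromosome 15 (67839971 to 67840839) had at least 11112 in SA, against 44, 41 and 68 in WT. The PGK1 promoter on chromosome X (78103747 to 78104396) had at least 23071 in SA, against 203, 274 and 281 in WT. The TBC1D5 intron region had at least 689 in SA and no WT call.

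A candidate explanation is that the SA cells or libraries contain introduced DNA that carries an RNF111 coding sequence, and promoter and other parts of a vector on the same or other molecules. Its reads would align to the human sequences of origin. All 13 RNF111 regions lay on exons or UTRs and 0 in introns, and the edges of these peaks differed between the 3 SA libraries by a median of 2 bp, against 46.5 bp in the strongest 1% of other regions called in every SA library. More genomic copies of the loci are argued against by the 66 peaks within 500 kb that all libraries share, whose median ratio of SA to WT, relative to all regions, was 1.12. More accessible chromatin is argued against by the first-exon peak of RNF111, where the highest SA pileup over floor was 0.927 of the lowest in WT. Relative to all regions, which were lower in SA, this peak was 1.93 times as high in SA, far below the factor of 20 of the regions above. Whether the DNA sits in the cells or was carried over into the libraries cannot be told apart, because no SA library lacks it. The highest over the lowest SA library was 1.36 for the RNF111 exons, against 1.37 in other shared regions, and 1.60 to 2.12 for the other 9 regions that stood out. These values do not tie the other 9 regions to the RNF111 sequence, and whether they lie on the same molecule was not tested.

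The genotype difference in called regions was set against other splits of the 6 libraries. The real split gave 35271 regions called on one side only, and the highest of the other splits 4659; 1 of the 10 splits, the real one, reached that number. For genes with a promoter peak the real value was 449 and the highest other 122, and again only the real split, 1 of 10, reached it. With 10 splits, no share under 0.05 is possible, so the splits cannot decide on chance. The real split also sets the longest lists (178779 peaks or more) against the shortest (133342 or fewer). A difference in list length alone can therefore raise its number, and the splits cannot separate that from genotype. The count of regions in every WT and no SA library was much lower at equal list length (below).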

How the results depend on the processing

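All alternatives were planned before the data were examined. Of 120 alternative values of the main results, 92 kept their direction or stayed within 1.5 times the main count, 27 counts moved further and 1 reversed; the cause was not tested unless named. With the strongest 59103 peaks of every list, regions called in every WT and no SA library numbered 7086 and in every SA and no WT library 826, genes with a promoter peak in every WT and no SA library 104 and in the other direction 87, genes with a promoter peak were 196 more in SA (reversed), 3 lists lay apart and 0 lists were enriched; by construction this removes most WT peaks. With -log10 q of at least 5, regions in every SA and no WT library were 50 and such genes 0. The genes called in every SA and no WT library numbered 2 with a window of 500 bp and 4 with the summit inside the window, and 0 lists were enriched with a window of 2 kb. Leaving out each library in turn gave 37432 to 60418 regions in every WT and no SA library, 165 to 1154 in the other direction, 489 to 897 genes in every WT and no SA library, 1 to 20 in the other direction, and 0 to 1 enriched lists. With a library left out the criterion is looser, so these counts of regions and genes can hardly fall. Their rise does not measure dependence on single libraries, and some of the 27 counts that moved are of this kind. In the leave-out runs the difference in peaks ranged from -154535 to -117416 and that in promoter share from 8.40 to 14.2 percentage points. Peak calls, relative to the genotype mean, gave no sign of pairing by replicate number (correlations of same-numbered libraries -0.0165, -0.0146 and 0.0167). Libraries with different numbers gave -0.0333 to 0.0398. This cannot show whether same-numbered libraries were prepared together. With the replicate block, the differences of SA from WT were the same, -131807 peaks, -35.2 Mb, 10.9 percentage points of promoter share and -1709 genes, each with a sign-flip p of 0.25, the smallest possible; 8 chromosomes and 12 lists lay apart. The 3 other splits that keep same-numbered libraries on opposite sides gave 673, 1291 and 2079 regions called on one side only, against 35271, and 18, 32 and 47 genes, against 449. These splits mix long and short lists, which the real split does not. Of 37 named genes, between 5 and 13 changed their share of libraries with a promoter peak under the other windows, thresholds and list length, and 0 reversed. The motif search and its window were not run, and the files hold only standard chromosomes, so using all contigs changes nothing. Depth is known only through the background floor.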

Other observations

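The tests of sequencing depth were chosen after the result was seen; those of the odds of being called and of strong regions were written before their results, the one at equal list length after the odds ratios of the full lists were seen. Sites away from promoters were called less often in SA than promoters of equal strength. WT replicate 2 peaks with pileups from 43 to 78 were called in SA replicate 1 in 73.7% of cases at promoters and 42.9% elsewhere, and in WT replicate 1 in 93.7% and 96.5%. Within 10 bins of WT pileup, the odds ratio of being called, promoter against other peaks, had a median of 4.36 over the 9 pairs of a WT reference and an SA library (3.82 to 5.34), and of 0.936 over the 6 pairs of WT libraries (0.815 to 1.02).

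Lower depth, in the sense of fewer reads in total, is argued against as the whole cause of the fewer SA peaks. Read filters and duplicate handling are not given, so the floor cannot show how many of the reads were usable. The floor of SA replicate 2 was 1.34 times the highest WT floor, yet it had fewer peaks than any WT library; the floor follows depth only if all libraries were called with the same settings, which is not stated. The floors of SA replicates 1 and 3 were below every WT floor, but under that condition depth scales pileup and floor alike, and the higher of their median ratios in shared regions was 0.443 of the lowest in WT. A loss of signal by 1 factor at every region is argued against by the odds ratios; the share of strong WT regions not called, 6.70% to 9.23% in SA and 1.52% to 3.92% in WT (lowest SA over highest WT 1.71), lay between the bounds set beforehand. List length accounts for part of the promoter excess: with every list at its 59103 strongest peaks the difference in promoter share was 3.75 instead of 10.9 percentage points. It is argued against as the whole cause, since the median odds ratio in these lists was 4.82 in SA (4.32 to 5.34) and 0.770 in WT (0.727 to 0.904).

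What stays open is a difference in cell state or library preparation between the genotypes that affects promoters less than other sites, and an effect of the RNF111 mutation on distal accessibility. The labels give no batch, and whether the genotypes were prepared side by side is not stated. It may be that the S254A cells lost accessibility mainly away from promoters (odds ratio 4.36), which is a hypothesis. Libraries prepared together would separate it from a difference in preparation. They would not separate it from a difference in cell state or from introduced DNA (below).

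A further hypothesis concerns what the 2 genotypes compare. RNF111 exon peaks were called in 3 SA and 0 WT libraries, and their edge spread of 2 bp (46.5 bp in other strong regions) and the median ratio of 1.12 at flanking peaks, tests chosen after the result was seen, may point to an RNF111 coding sequence in SA that WT lacks. The comparison would then be between cells with and without introduced DNA as well as between protein forms. Reads that join RNF111 exons or cross into vector sequence, looked for in the raw reads of both genotypes, would test this. The same reading may hold for CDC20, whose gene span and pseudogene carried high pileups in each SA library; whether CDC20 was introduced on purpose is not stated in the labels.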
